A study of Mus musculus with 6 samples.

How the data were processed

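RNA was measured in the ventral posterolateral and ventral posteromedial nuclei (VPL/VPM), the somatosensory relay of the thalamus, of wild-type C57 mice 14 days after an injection into the right side. The 6 libraries fall into 2 groups of 3. One group received 10 nL of type IV collagenase (0.01 U), an enzyme that opens the basement membrane of vessels and so causes a small haemorrhage, and the other group 10 nL of saline. Groups and replicate numbers were taken from the sample titles. The labels do not say whether a library came from 1 animal or from pooled animals, so the p-values measure the spread between these samples. No uninjected tissue and no treated animals were analysed here.

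Per the labels' protocols, mRNA was captured on oligo(dT) beads, fragmented, copied with random hexamer primers and amplified by PCR, and no step that marks the strand is named. Whether reads of a gene and of an overlapping gene on the opposite strand can be told apart is therefore not known. The submitters' processing notes name FastQC, HISAT2 2.2.1, StringTie, DESeq2 and the genome build GRCm38, without roles or order. The annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. The authors deposited, per the file headers, a raw count and an FPKM value for each feature in each library. The counts were whole numbers and were used for every test; the deposited FPKM values served only to check the counts, as described below.

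Each file held the same 26554 features, of which 22036 carried an Ensembl identifier and 4518 were new loci assembled by the authors. Functional annotation text had spilled onto lines of its own in the files (10 to 30 lines per library), and those lines were skipped. In the files 27 gene names had been turned into dates, so symbols were taken from a reference table by Ensembl identifier, which matched 22022 identifiers. Positions came from GENCODE M21, which uses GRCm38. A count of 0 in all 6 libraries was found for 3806 features.

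Total counts were 44363142, 33603076 and 37989573 in saline replicates 1, 2 and 3, and 44815451, 36463551 and 38507070 in collagenase replicates 1, 2 and 3. A gene with 0 counts in all saline libraries was set against a floor of 3 counts over the whole saline group, which is 0.0266 CPM, the usual depth-scaled count. Ratios for genes with 1 to 3 saline counts in total carry an exact 95% interval. PCR reads are not independent molecules, so the floor and these intervals cover counting error only.

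Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, libraries were scaled by TMM factors (0.898 to 1.063), and groups were compared with the robust quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over 17240 tested genes and a threshold of 0.05. Of the tested genes 1721 were new loci. Fold changes are collagenase over saline with the standard error of the fit, and levels are TMM-scaled CPM with the SD over 3 libraries. Gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Of 46 lists of cell type and pathway genes, 44 had at least 5 tested members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Adjusted p-values of camera cover the 44 lists. Camera with an estimated correlation and fry were run beside it. The lists of B cells and of sex-linked genes had 4 tested members each and were not tested.

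Named genes are Pik3cg and Nlrp3, which the series title names, and the 10 largest rises and 10 largest falls among genes that passed. Those had to have a mean log2 CPM of at least 1 and no overlap between groups, and predicted loci were left out. Up to 3 members with the smallest p were added from each list. Some genes that the rule takes are not reported here. Every gene named outside this rule was chosen after the values were seen, also where this is not said beside it. Members of families with near-identical sequence, such as Tgtp1, the Ifit, Oas and Gbp genes, the class II and other H2 genes and the haemoglobin genes, may share reads and their counts are uncertain.

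The steps were tested on simulated data: 20 sets of counts for the real genes, each with 200 genes changed. With each gene's own estimated dispersion, 59.9% of genes changed 2-fold and 87.9% of those changed 4-fold were called on average. Unchanged genes made up 8.64% of the calls on average (4.64% to 12.2% over the sets), which is above the nominal level of the 0.05 threshold. With dispersions taken from the fitted trend the share was 5.16%. A first simulated set had reached the bound on false calls set in advance and so failed it, and the 20 sets were then run and are all included; that bound was dropped, and the fitting code and threshold were left as they were. Camera called 0.05 lists per set on average, but simulated genes were independent within lists, so this does not cover lists whose genes move together.

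The length implied by each gene's count and FPKM was compared between libraries. It differed over 1.5 times for 250 of 16526 genes with at least 20 counts in at least 2 libraries, and for 5 of 405 called genes. Ifit2 was among the 250, with a 5.42-fold difference.

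The alternatives were DESeq2 size factors, library totals, no filter, a stricter filter, leaving out each library, the replicate number as a block, the DESeq2 1.42.0 Wald test, limma-voom and other thresholds. Chosen after seeing the data were the fits without replicate 3 of both groups, with a choroid plexus score or a hippocampal and cortical score as a covariate, without new loci and mitochondrial genes, and without genes of unequal implied length. Pathway enrichment used the KEGG terms in the authors' deposited annotation and was also chosen after seeing the data.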

Results

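The series asks which genes differ in the somatosensory thalamus in a mouse model of central post-stroke pain, in which collagenase causes a small thalamic haemorrhage. Its title names PIK3CG and NLRP3. The data are 6 poly(A) RNA libraries from VPL/VPM tissue at 14 days, 3 after collagenase and 3 after saline, with total counts from 33603076 to 44815451.

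At 14 days after collagenase, 19 of 24 tested genes of disease-associated microglia, 21 of 23 of phagocytosis, 18 of 27 of lysosomes, 11 of 20 of complement and 9 of 20 of antigen presentation rose, and 11 of 25 interferon response genes fell. Some lists share genes, so these counts overlap: Gpnmb and Cd68 are on the microglia and lysosome lists, and Clec7a on the microglia and phagocytosis lists. Camera called these lists with its preset correlation. With an estimated correlation camera called 0 of the 44 lists (adjusted p from 0.079 to 0.17 for these lists). Fry, which tests a list by itself rather than against other genes, called these lists (adjusted p from 0.0036 to 0.029). Gpnmb, a membrane glycoprotein of lipid-laden phagocytes, rose from 1.30 ± 0.245 to 114.6 ± 49.1 CPM (SD, n = 3 per group), a log2 fold change of 6.45 with a standard error (SE) of 0.39. Cd74, the invariant chain of class II antigen presentation, rose from 4.06 ± 0.520 to 73.2 ± 18.1 CPM. Ifi44, an interferon-stimulated gene, fell from 15.9 ± 1.08 to 2.29 ± 0.766 CPM, a log2 fold change of -2.78 with an SE of 0.24.

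In total 416 of 17240 tested genes passed the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these, 366 were higher and 50 lower after collagenase, and 310 and 30 of them changed by at least 1 on the log2 scale. All 416 had no overlap between groups, as did 3039 tested genes (17.6%), where chance gives 10%. The count depended on single libraries: it was 85 without saline replicate 1, 917 without saline replicate 3, and 207, 142 and 213 without collagenase replicates 1, 2 and 3. The count of lower genes moved from 50 to 4 without saline replicate 1 and to 414 without saline replicate 3. In simulated data with the genes' own dispersions, 8.64% of calls were unchanged genes, above the nominal level of the threshold.

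The title genes differed in their result. Pik3cg (ENSMUSG00000020573, chromosome 12, 32173473 to 32208659, minus strand, GRCm38), the catalytic gamma subunit of phosphoinositide 3-kinase found mainly in leukocytes, rose from 2.07 ± 0.364 to 6.71 ± 1.91 CPM (SD, n = 3 per group). Its log2 fold change was 1.69 with an SE of 0.26 and an adjusted p of 0.0155 in the edgeR quasi-likelihood test. Without saline replicate 1 the log2 fold change was 1.83 and the edgeR adjusted p 0.0712. Nlrp3 (ENSMUSG00000032691, chromosome 11, 59541568 to 59566956, plus strand), the sensor of an inflammasome, did not pass: it measured 0.930 ± 0.282 CPM in saline and 1.36 ± 0.547 CPM in collagenase libraries. Its log2 fold change of 0.55 had a 95% interval of -0.37 to 1.48 and an edgeR adjusted p of 0.678, and its values overlapped between groups. The interval includes both no difference and a rise of over 2-fold on the linear scale, so whether Nlrp3 differed stays undetermined.

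**Figure D1:**
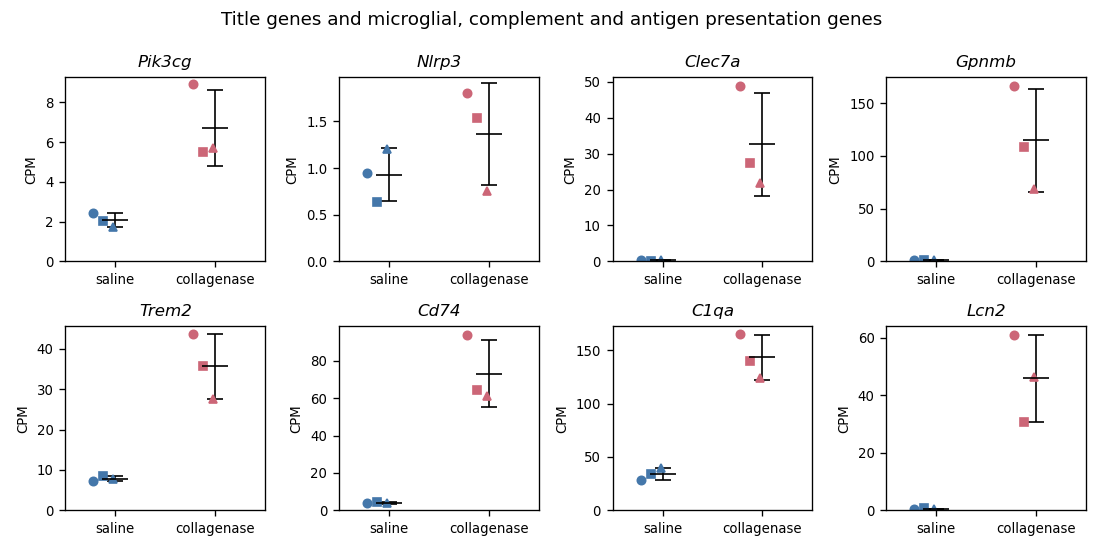
Levels in CPM (vertical axes, from 0) of 8 genes in saline (blue) and collagenase (red) libraries; circles, squares and triangles are replicates 1, 2 and 3, and black lines are the mean and SD of 3 libraries. Pik3cg lies between 1.73 and 2.46 CPM in saline and between 5.51 and 8.91 CPM in collagenase libraries, while the Nlrp3 values of the groups overlap.

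Of the 27 tested genes of PI3K and AKT signalling, 5 rose, 0 fell and 22 did not pass; adjusted over the list alone the count was also 5. The 5 were Vav1, Pik3cg, Btk, Pik3r5 and Inpp5d, all genes expressed mainly in blood-derived and microglial cells. Vav1, an exchange factor of immune receptors, rose from 2.37 ± 0.299 to 8.32 ± 2.64 CPM, and Btk, a kinase of B cells and myeloid cells, from 0.751 ± 0.0898 to 2.86 ± 0.931 CPM. The list's median log2 fold change was 0.02, and camera gave an adjusted p of 0.02, or an adjusted p = 0.49 with an estimated correlation. The call of Btk ended in 3 of the 6 fits that left out a library and that of Vav1 in 1. The camera adjusted p was 0.12 without saline replicate 2, 0.055 without saline replicate 3 and 0.054 without collagenase replicate 1.

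Among 21 tested inflammasome genes 4 rose and 17 did not pass; adjusted over the list alone, 15 rose. The 4 were Pycard, Il1rn, Mefv and Il18bp. Pycard, the adaptor that links sensors to caspase-1, rose from 2.85 ± 0.448 to 5.90 ± 0.727 CPM. Il1rn and Il18bp encode proteins that block interleukin-1 and interleukin-18. Mefv, which encodes pyrin, had 0 counts in saline and was at least 16.8-fold higher in collagenase libraries. Casp1 measured 0.917 ± 0.153 and 2.17 ± 0.548 CPM and did not pass (edgeR adjusted p 0.087), and Il1b, at 0.205 ± 0.115 and 0.846 ± 0.0623 CPM, did not pass either (edgeR adjusted p 0.0724). The median log2 fold change was 0.68; the camera adjusted p was 5.7e-11, or an adjusted p = 0.098 with an estimated correlation. The calls of Pycard and Mefv ended in 5 of the 6 fits that left out a library, and that of Il1rn in 4.

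The microglial lists held members that rose and members that did not pass. Tissue RNA does not tell microglia from macrophages that entered from blood, and Lyz2 and Ccr2 of the monocyte list rose as well. Of 24 tested genes of disease-associated microglia, a state of microglia seen near damaged tissue, 19 rose and 5 did not pass, and 23 rose adjusted over the list alone. Clec7a, a receptor for beta-glucan, rose from 0.263 ± 0.0517 to 32.7 ± 14.3 CPM (log2 fold change 6.93, SE 0.40), and Itgax, an integrin, had a log2 fold change of 5.60 with an SE of 0.37. Cst7, a cystatin with saline counts in replicate 1 alone, rose to 11.6 ± 3.29 CPM (log2 fold change 7.76 to 11.80 over fits without a library), and Atp6v0d2, a subunit of the lysosomal proton pump, had 0 counts in saline and was at least 272-fold higher. Of 15 genes of homeostatic microglia 6 rose and 9 did not pass, and 9 rose adjusted over the list alone. Trem2, a lipid receptor of microglia, had a log2 fold change of 2.19 (SE 0.18) and Fcrls of 1.29 (SE 0.13). P2ry12, a purine receptor of resting microglia, measured 31.0 ± 8.91 and 34.7 ± 0.362 CPM and did not pass. The median log2 fold changes of the lists were 2.25 and 0.52, and each had an adjusted p = 0.079 with an estimated correlation in camera.

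Genes of phagocytosis and Fc receptors showed the highest share of members that passed: 21 of 23 rose, and 22 adjusted over the list alone. Fcgr2b, an inhibitory receptor for IgG, rose from 3.13 ± 0.852 to 23.6 ± 4.06 CPM. Of 27 lysosome genes 18 rose (21 adjusted over the list alone), among them Cd68, a lysosomal protein of macrophages, with a log2 fold change of 2.54 (SE 0.23), and the protease Ctsh with 1.63 (SE 0.15). Of 20 complement genes 11 rose (16 adjusted over the list alone). The C1q chains C1qa, C1qc and C1qb, which start the classical pathway, had log2 fold changes of 2.07, 1.86 and 1.83. Of 20 antigen presentation genes 9 rose (13 adjusted over the list alone), led by Cd74 and the class II genes H2-Ab1 and H2-Eb1, with log2 fold changes of 4.17, 4.17 and 3.50. With an estimated correlation the camera adjusted p was 0.079 for phagocytosis and for complement, 0.1 for lysosome and 0.16 for antigen presentation. The fry adjusted p was 0.0036 for phagocytosis and for complement, 0.0048 for lysosome and 0.011 for antigen presentation.

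Part of the genes of blood-derived immune cells rose, from saline levels between 0 counts and 39.7 ± 6.67 CPM (Fn1). Of 13 tested genes of T and NK cells 7 rose, and 11 adjusted over the list alone. Cd8a, a co-receptor of cytotoxic T cells, had 0 counts in saline and 1.85 ± 1.17 CPM in collagenase libraries, at least 69.7-fold higher (44.6-fold without collagenase replicate 1). Cd3g was at least 31.5-fold higher, and Il2rb had a log2 fold change of 3.57 (SE 0.47). Of 12 listed neutrophil genes only 6 had counts enough to be tested, and 3 of these rose (4 adjusted over the list alone): Lcn2, Csf3r and Mmp8. Mmp8, a collagenase of neutrophils, measured only 0.476 ± 0.122 CPM in collagenase libraries, at least 17.9-fold above the saline floor. Lcn2, also made by astrocytes, rose from 0.528 ± 0.0975 to 45.8 ± 15.1 CPM, and Csf3r was already at 5.89 ± 1.43 CPM in saline. The 3 genes therefore do not by themselves show the presence of neutrophils. Of 17 genes of monocytes and border macrophages 4 rose (9 adjusted over the list alone), including the lysozyme gene Lyz2 with a log2 fold change of 5.12 (SE 0.37), Ccr2 with 3.67 (SE 0.57; 3.03 to 4.02 over fits without a library) and Fn1 with 0.98 (SE 0.15). Jchain, the joining chain of secreted antibodies, rose among the 4 tested B cell genes, from 0.644 ± 0.336 to 7.19 ± 2.22 CPM. Of the 6 fits that left out a library, 4 ended the call of Mmp8, 3 that of Fn1, 2 those of Cd8a, Cd3g and Ccr2, and 1 those of Il2rb and Jchain. The camera adjusted p with an estimated correlation was 0.079 for T and NK cells and for neutrophils, and 0.12 for monocytes.

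Of 22 reactive astrocyte genes 12 rose and 10 did not pass, and 17 rose adjusted over the list alone. Serpina3n, a secreted protease inhibitor, rose from 17.0 ± 6.20 to 322.6 ± 20.6 CPM, and Tgm1, a transglutaminase, from 0.0300 ± 0.0520 to 7.65 ± 1.94 CPM, its saline counts all lying in replicate 1 (log2 fold change 7.16 to 11.20 over fits without a library). Of 15 astrocyte identity genes only Aqp4, the water channel of astrocyte endfeet, rose (log2 fold change 0.82, SE 0.15); adjusted over the list alone the count was 2. Of 25 genes of fibroblasts and extracellular matrix 10 rose, and 19 adjusted over the list alone. Mmp3 and Mmp12, proteases of the matrix, had 0 counts in saline and were at least 349-fold and at least 220-fold higher, and Col1a2, a collagen chain, had a log2 fold change of 1.26 (SE 0.19). Anpep, an aminopeptidase, was the member among 13 pericyte and smooth muscle genes that rose (log2 fold change 1.66, SE 0.20), with 2 members adjusted over the list alone. In collagenase replicates 1, 2 and 3 Mmp3 measured 17.4, 6.51 and 3.89 CPM, and without replicate 1 it was at least 195-fold higher. Of the 6 fits that left out a library, 4 ended the call of Aqp4, 4 that of Mmp3, 3 that of Col1a2 and 2 that of Mmp12. With an estimated correlation the camera adjusted p was 0.079 for reactive astrocytes, 0.12 for astrocyte identity (also 0.12 without saline replicate 2 at the preset correlation), 0.1 for extracellular matrix and 0.12 for pericytes.

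Of 21 cytokine and chemokine genes 7 rose (13 adjusted over the list alone), among them Cxcl16 with a log2 fold change of 2.73 (SE 0.30) and Ccl6 with 2.58 (SE 0.29). Cxcl9, with 2 saline counts, had a ratio of 80.9 with a counting interval of 22.1 to 674. Of 25 Toll-like receptor and NF-kB genes 9 rose (17 adjusted over the list alone), including Cd14, Tlr2 and Tnfrsf1a with log2 fold changes of 1.91, 2.26 and 0.86. Of 22 genes of haem and iron handling 7 rose (8 adjusted over the list alone), such as Slc11a1, a metal transporter of phagosomes, at 2.78 (SE 0.20), and Cp, ceruloplasmin, at 1.09 (SE 0.12). Of 21 genes of lipid transport and storage 5 rose (14 adjusted over the list alone). Apoe rose from 1440.0 ± 218.7 to 3663 ± 220.6 CPM, and Abca1, a cholesterol exporter, had a log2 fold change of 1.21 (SE 0.17). With an estimated correlation the camera adjusted p was 0.1 for the Toll-like receptor list and 0.079 for the cytokine, iron and lipid transport lists. The acute-phase gene Saa3, with 2 saline counts, had a ratio of 294 with a counting interval of 81.2 to 2440, and the macrophage gene Cd5l, with 3 saline counts, a ratio of 396 with an interval of 135 to 1920. The saline counts of Cxcl9, Saa3 and Cd5l all lay in replicate 1, and over fits without a library their log2 fold changes ranged from 5.63 to 8.75, 7.30 to 10.58 and 7.31 to 11.55. Cd5l measured 19.9, 7.88 and 1.48 CPM in collagenase replicates 1, 2 and 3, and its call ended in 4 of the 6 fits that left out a library, that of Tnfrsf1a in 3 and that of Abca1 in 1.

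Genes of the interferon response list were lower after collagenase as a set, against the direction of the other immune lists. The log2 fold change was negative for 24 members and positive for 1, Cxcl10. Of 25 tested members 11 fell, 0 rose and 14 did not pass, and 21 fell adjusted over the list alone; the median log2 fold change was -1.19. Ifit1, which binds viral RNA, fell from 24.7 ± 5.06 to 5.65 ± 1.44 CPM (log2 fold change -2.13, SE 0.23), and Irf7, a transcription factor of the interferon response, from 36.7 ± 2.52 to 8.87 ± 4.20 CPM (log2 fold change -2.04, SE 0.30). Iigp1, an interferon-inducible GTPase, had a log2 fold change of -1.60 (SE 0.21). Of the 10 largest falls 9 were interferon-stimulated genes: Ifi44, Rsad2, Oasl1, Tgtp1, Ifit1, Isg15, Irf7, Usp18 and Ifit3. The exception was Kcnv1, a modulatory potassium channel subunit, which fell from 8.51 ± 3.55 to 2.21 ± 0.814 CPM. The camera adjusted p of the list was 8.6e-20, or an adjusted p = 0.17 with an estimated correlation. Ifit2 counts were 2107, 1401 and 32 in saline and 1149, 25 and 785 in collagenase libraries, and their ratio to FPKM differed 5.42-fold between libraries, so its level is uncertain. The calls of Ifi44 and Ifit1 held in all 6 fits that left out a library; that of Irf7 ended without saline replicate 1 or collagenase replicate 3 (highest edgeR adjusted p 0.0778). The calls of Oasl1, Tgtp1, Ifit3 and Kcnv1 ended in 4 of these fits, those of Isg15 and Usp18 in 3 and those of Rsad2 and Iigp1 in 2.

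**Figure D2:**
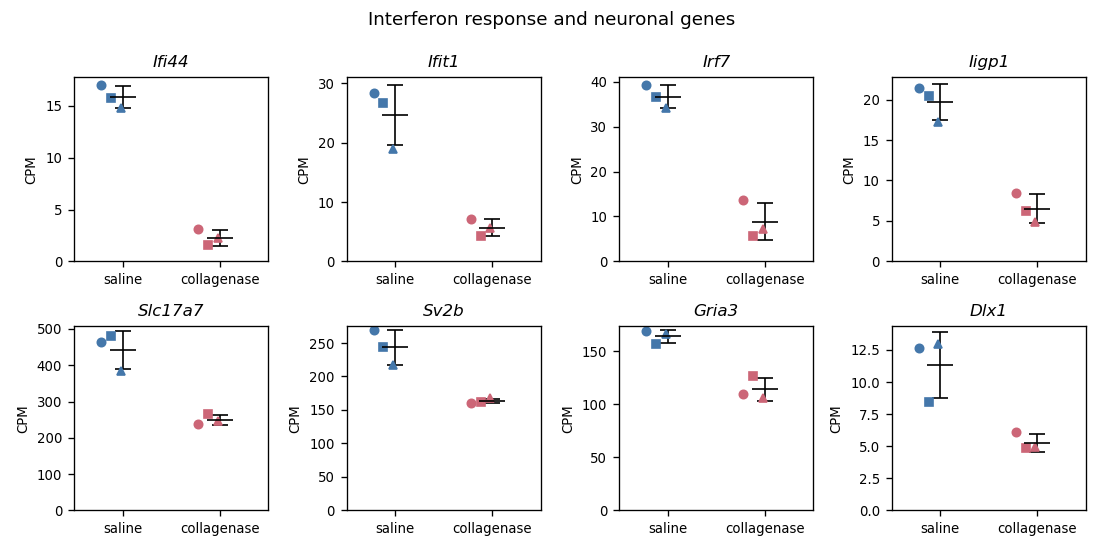
Levels in CPM (vertical axes, from 0) of 4 interferon response genes and 4 neuronal genes in saline (blue) and collagenase (red) libraries; circles, squares and triangles are replicates 1, 2 and 3, and black lines are the mean and SD of 3 libraries. In each of the 8 panels the 3 collagenase libraries lie below the 3 saline libraries.

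Few members of the neuronal lists passed, and list medians went in both directions. The median log2 fold change was -0.81 for GABAergic and reticular genes, -0.72 for hippocampal and cortical genes, -0.99 for striatal genes (list not called) and 1.00 for habenular genes. Slc17a7, a vesicular glutamate transporter, fell from 442.6 ± 52.0 to 249.2 ± 13.6 CPM (log2 fold change -0.83, SE 0.12). It was the member that fell among 16 hippocampal and cortical genes, with 3 adjusted over the list alone. Its level need not come from such tissue: in saline replicate 3 it measured 383.4 CPM, where Neurod6 of the same list measured 0.176 CPM. Dlx1, a transcription factor of inhibitory neurons, fell among 14 GABAergic and reticular genes (log2 fold change -1.10, SE 0.21), with 2 adjusted over the list alone, where 1 other rose. Gria3, an AMPA receptor subunit, fell among 17 glutamate receptor genes (log2 fold change -0.52, SE 0.10; 2 adjusted over the list alone), and Sv2b, a synaptic vesicle protein, among 22 vesicle release genes (log2 fold change -0.58, SE 0.11; 1 adjusted over the list alone). Of 17 pan-neuronal genes, 20 thalamic relay genes and 25 thalamic ion channel genes 0 passed, with median log2 fold changes of -0.19, -0.20 and -0.14; adjusted over the list alone 1 relay gene fell. Slc17a6, a glutamate transporter on the relay list, chosen after its values were seen, measured 520.5 ± 116.5 and 490.8 ± 72.6 CPM and did not pass. With an estimated correlation the camera adjusted p was 0.18 for hippocampal and cortical, 0.26 for GABAergic, 0.12 for glutamate receptor, 0.19 for vesicle release, 0.49 for pan-neuronal, 0.64 for relay and 0.46 for ion channel genes. Without saline replicate 3 the camera adjusted p was 0.85 for relay, 0.26 for pan-neuronal and 0.091 for ion channel genes; without collagenase replicate 1 it was 0.26 for relay and 0.23 for pan-neuronal genes, and without saline replicate 1 it was 0.068 for relay genes. The calls of Gria3 and Sv2b ended in 5 of the 6 fits that left out a library, and those of Slc17a7 and Dlx1 in 4.

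Further lists called lower were myelin (0 of 16 passed, median log2 fold change -0.16), cholesterol synthesis (0 of 20, -0.20; 3 fell adjusted over the list alone) and oxidative phosphorylation (0 of 25, -0.18). Their camera adjusted p with an estimated correlation was 0.49, 0.079 and 0.49. Habenular genes were called higher with 0 of 11 members that passed and an adjusted p = 0.49 with an estimated correlation. Without collagenase replicate 3 the camera adjusted p was 0.062 for habenular and 0.33 for myelin genes, and without saline replicate 3 it was 0.12 for myelin genes. Lists not called were erythroid cells, oligodendrocyte precursors, striatal and hypothalamic neurons, choroid plexus, ependymal and endothelial cells, oxidative stress, GABA receptors, pain-associated genes, immediate early genes, cell cycle and mitochondrially encoded genes. Single members of these rose: Nfe2l2, a regulator of antioxidant genes (log2 fold change 0.68, SE 0.12), the chemokine receptor gene Cxcr4 in the pain list (1.59, SE 0.30) and Atf3, an injury-induced transcription factor, in the immediate early list (2.96, SE 0.35). The calls of Nfe2l2 and Cxcr4 ended in 5 of the 6 fits that left out a library. For oligodendrocyte precursors, choroid plexus and oxidative stress the median and the camera direction differed in sign. Of 4 tested sex-linked genes 0 passed.

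**Figure D3:**
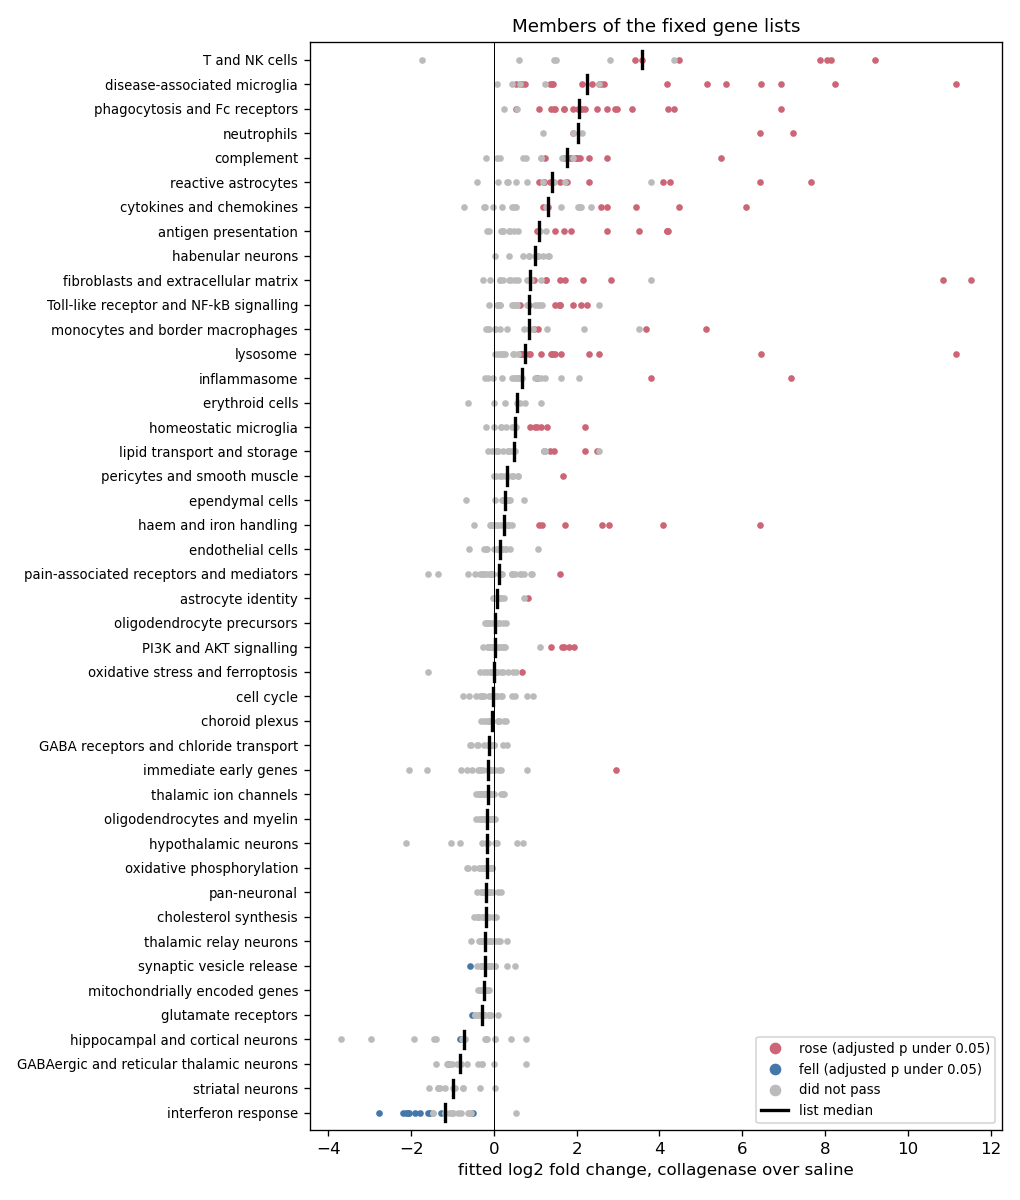
Fitted log2 fold change of collagenase over saline (horizontal axis) for each tested member of the 44 tested lists (vertical axis), with members that rose in red, those that fell in blue and those that did not pass in grey; black bars are list medians. Medians run from 3.57 for T and NK cells to -1.19 for interferon response, and points of genes with 0 saline counts depend on the prior count of the fit.

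In all, camera with the preset correlation called 31 of 44 lists, 20 higher and 11 lower, and with an estimated correlation it called 0. For neutrophil genes the estimated correlation was -0.026, below the preset 0.01, yet the camera p was 2.8e-10 preset and 0.0029 estimated. The count of 0 therefore does not by itself show that genes moving together account for the calls. Fry called 21 of the 31. The 10 others were PI3K and AKT, habenular, pan-neuronal, relay, ion channel, GABAergic, hippocampal and cortical, vesicle release, myelin and oxidative phosphorylation genes. Other splits of the same 6 libraries gave up to 25 called lists with the preset correlation, so a list call at that setting does not by itself set the real groups apart from other splits.

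The libraries also differed in markers of neighbouring tissue. Ttr, the main transcript of choroid plexus, measured 847, 2382 and 12.9 CPM in saline replicates 1, 2 and 3 and 1669, 1853 and 10.2 CPM in collagenase replicates 1, 2 and 3. Drd2, a dopamine receptor of striatal neurons, measured 70.8 CPM in saline replicate 3 and 11.8 to 20.4 CPM in the other libraries. The mean log2 CPM of habenular genes was 1.75 and 2.15 in saline replicates 1 and 2 and 3.46 to 4.86 in the other 4 libraries. Mitochondrial transcripts made up 15.9% of counts in saline replicate 3 and 7.48% to 11.7% in the others. The first principal component held 41.2% of the variance and separated the groups, and the second, with 27.4%, set saline replicate 3 apart.

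**Figure D4:**
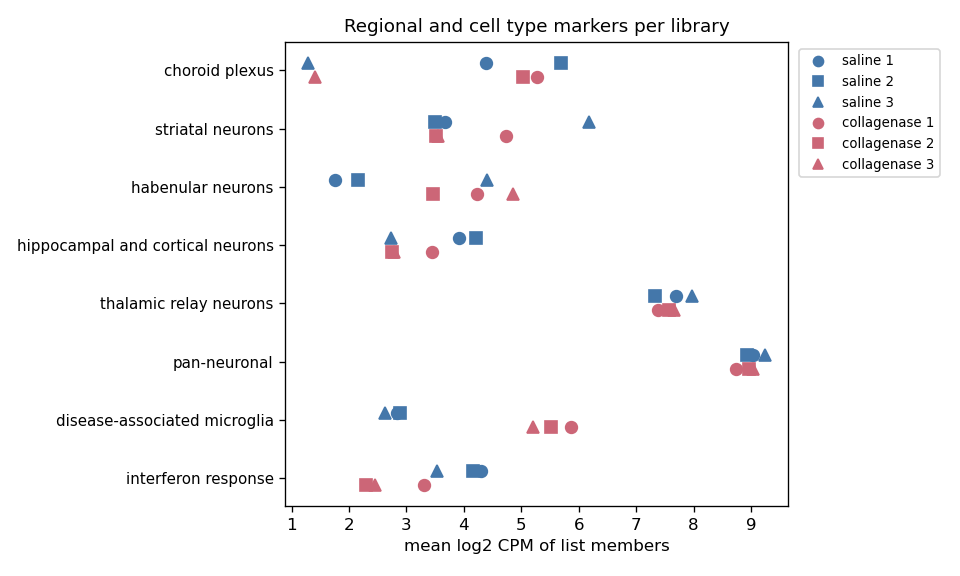
Mean log2 CPM of the members of 8 gene lists (horizontal axis) in each library, with saline in blue, collagenase in red and replicates 1, 2 and 3 as circles, squares and triangles. Choroid plexus genes are at 1.29 and 1.41 in replicate 3 of the groups and between 4.39 and 5.69 in the other libraries, while disease-associated microglia genes separate the groups.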

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

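Tests chosen after seeing the data are those without replicate 3 of both groups, with a score as a covariate, or without a class of genes. Leaving out single libraries gave 85 to 917 genes (81 to 503 higher, 4 to 414 lower) and 28 to 34 lists; these fits have fewer samples, and the cause of the rise without saline replicate 3 was not tested. DESeq2 called 813 genes (616 higher, 197 lower). Library totals called 29 lower genes. A fold threshold left 30 lower genes, and unadjusted p gave 2075 genes (1282 higher, 793 lower). Without replicate 3 of both groups the counts were 1034, 608 and 426. With the choroid plexus score 105 genes were lower, and with the hippocampal and cortical score 818 genes were called, 564 higher and 254 lower. The list count was 0 with an estimated correlation. The replicate block gave 302 genes and 30 lists. The correlations of same-numbered samples were 0.044, 0.107 and 0.203 for replicates 1, 2 and 3. Replicates 2 and 3 of each group correlated best with their own number and replicate 1 did not. Replicate 3 of both groups also shared low choroid plexus genes, so whether the numbers pair samples is not settled. The log2 fold change of Pik3cg ranged from 1.43 to 1.83 over fits without a library and that of Nlrp3 from 0.29 to 0.85. Of 69 reported named genes that passed, 34 passed in all 6 such fits. Values of reported genes that changed sign had not passed: Otx2 ranged from -0.09 (without saline replicate 3) to 0.85 over fits without a library, and Ddx3y ranged from -0.26 to 0 over fits without a library and was 0.19 with the hippocampal and cortical score. The alternatives for normalized values, a pseudocount and sample weights, were not run because the files hold counts.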

Other observations

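Tests chosen after the result was seen were those on transcript models, on microglia, on a uniform loss of neurons and on choroid plexus tissue, and the pathway enrichment. KEGG terms in the authors' deposited annotation gave a view of the calls without fixed lists, against 7330 tested genes with a term. Of 321 pathways 62 were enriched among higher genes (one-sided hypergeometric test with Benjamini-Hochberg adjustment). Phagosome held 31 higher genes where 5.09 would be drawn by chance (adjusted p 1.8e-14), and osteoclast differentiation held 24 where chance gives 3.70 (adjusted p 5.0e-12). The PI3K-Akt pathway held 25 where chance gives 10.1 (adjusted p 1.9e-04). Among its 25 genes were cytokine receptor, collagen and integrin genes, and the PI3K subunit genes were Pik3cg and Pik3r5 alone. In the fixed PI3K and AKT list 22 of 27 genes did not pass. The hypergeometric test treats genes as independent, so its p-values do not cover genes that move together. Among lower genes 2 pathways were enriched, hepatitis C and influenza A, through interferon-stimulated genes such as Irf7, Rsad2 and Stat2. Influenza A was enriched among higher genes as well, with 12 where chance gives 4.48 (adjusted p 0.0095).

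Other neuronal genes, picked after their values were seen, also fell: Camk2a, a kinase of excitatory synapses, from 810.1 ± 29.8 to 566.6 ± 11.2 CPM, and Neto1, an auxiliary subunit of kainate receptors, from 25.1 ± 4.43 to 9.08 ± 2.34 CPM. Cd4 measured 13.1 CPM in saline replicate 3, where Cd3e had 0, and 0.378 to 2.94 CPM in the other libraries. Neurod6, a cortical and hippocampal gene, ranged from 0.176 to 39.8 CPM in saline and from 0.538 to 3.66 CPM in collagenase libraries. Hmox1, which breaks down haem, rose from 4.03 ± 1.24 to 13.2 ± 2.69 CPM, while the haemoglobin gene Hbb-bs measured 74.9 ± 25.2 and 116.5 ± 63.4 CPM and did not pass.

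Of 25 interferon response genes 11 fell in collagenase libraries, while part of the genes of the other immune lists rose. Cortical or hippocampal tissue in the saline libraries is argued against only weakly as the whole cause. With the hippocampal and cortical score as a covariate, the interferon score still differed by -0.90 (SE 0.27, 6 libraries), against -1.31 (SE 0.39) without it. Both scores were lowest among saline libraries in replicate 3 and highest among collagenase libraries in replicate 1, so a share from such tissue stays open. For the 11 members that fell, counts moved between transcript models are argued against too, since 0 of them had an unequal implied length. Members that did not pass are not covered, and Ifit2, whose implied length was unequal, was among these. Reads moved to another gene would lower count and FPKM together, so the implied length cannot show them. A loss of microglia is argued against by the median log2 fold change of 0.52 of homeostatic microglia genes, 14 of 15 of them positive. It stays open, and untested without uninjected tissue, whether collagenase lowered these genes or the saline libraries had raised ones.

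Members of the neuronal lists that fell were Slc17a7, Dlx1, Gria3 and Sv2b, 4 of 173 tested, and 0 rose. The pan-neuronal median log2 fold change was -0.19 (SD 0.15 over members), while the median of the 4 genes was -0.70. The 4 genes were picked because they passed as lower, so their median had to lie below that of an unselected list. The pan-neuronal values thus argue only against a uniform loss of neurons as large as the fall of the 4 genes. A smaller uniform loss stays open. With the hippocampal and cortical score as a covariate (without Slc17a7), 4 of the 4 genes stayed lower by more than 2 standard errors. The differences were -0.74 (SE 0.11) for Slc17a7 and -1.17 (SE 0.28) for Dlx1. Genes called without overlap between groups are unlikely to follow a score that varies within groups. The fit therefore argues only weakly against cortical or hippocampal tissue in the saline libraries as the whole cause. Striatal tissue was not tested as a cause, and striatal genes were highest in saline replicate 3 (mean log2 CPM 6.18, against 3.49 to 4.74 in the other libraries). A change within particular neurons and a difference in which thalamic nuclei were dissected both stay open.

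Choroid plexus genes were low in replicate 3 of both groups. Of 13 members 12 had their 2 lowest values in those libraries, and a candidate explanation is that choroid plexus tissue was missing from those dissections. With the choroid plexus score as a covariate 577 genes were called, 412 of the 416 among them. The score was 3.79 ± 2.26 in saline and 3.90 ± 2.17 in collagenase libraries, and the 416 genes had no overlap between groups. A covariate so balanced could hardly end their calls, so this count decides nothing. The test first written, on direction, is not used for the same reason. Only the near-equal score itself argues against choroid plexus content as the whole source of the called differences. Why these genes were low in replicate 3 stays open, and no biological explanation of it was tested.

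The real split gave 416 genes and the highest of the other splits 1; for lists the real split gave 31 and the highest other 25. With 10 splits of 6 libraries a share under 0.05 cannot be reached, so they are too few for a statement on chance.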
